A study of Mus musculus with 8 samples.

How the data were processed

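RNA was measured by sequencing in 6 libraries of proerythroblasts, the earliest red cell precursors that can be recognised by their shape, sorted from mouse bone marrow. Per the labels, the mice were of the C57BL/6 strain, received 4 injections of pI:pC at 15 mg/kg, and were killed 2 weeks later. The samples form 3 groups of 2 libraries each: WT (floxed Chd8 and p53 alleles in the genotype label), P53KO (p53 deleted) and DKO (Chd8 and p53 deleted). The series also lists 2 CHD8 CUT&RUN samples from wild-type erythroblasts, which were not analysed here.

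The values are TPM (transcript abundance, scaled for gene length and to a fixed library total) per gene as deposited, in a single table with 1 column per library. Each deposited TPM column sums to 1000000, and neither read counts nor sequencing depth can be recovered from them. The submitters' processing notes name Trim Galore 0.6.6, Bowtie2 2.4.2, Picard 2.23.8, SEACR and DESeq2 and the build GRCm38 (mm10), without saying which of these served the RNA libraries. The program that gave the TPM values, the annotation and the strand setting are not given in the sources used here. The table has 33641 rows, of which 12557 are 0 in all libraries. In 26 rows the gene symbol has been turned into a date, and 2 names occur more than once. A last column without a name holds 5 short notes and was not used. Sept9, Hbb-b1, Hbb-b2, Ahsp and Xist are not among the symbols as written.

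The design fixed before the data were examined had assumed read counts and a count-based quasi-likelihood test. Since the values are TPM, limma was used in its place. The TPM values were divided by composition factors between 0.9576 and 1.071 and are then called scaled TPM. The factors were computed without weights by trimming 30% of the log ratios and 5% of the mean levels (the TMM method). Genes with at least 0.5 TPM as deposited, before this scaling, in at least 2 libraries were tested, which left 12588 genes. Tests ran on log2(scaled TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), with all 6 libraries in 1 fit and no covariate, for 3 comparisons: P53KO vs WT, DKO vs P53KO and DKO vs WT. The fit had 3 residual and 3.36 prior degrees of freedom. All p-values are two-sided unless stated, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A log2 fold change is on the log2(scaled TPM + 1) scale and understates the change of low genes. Means are given ± SD over the 2 libraries of a group (n = 2) and log2 fold changes ± SE. The labels do not say that the libraries come from separate animals, so the p-values measure only the spread between these samples, which may be technical.

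Before the data were examined, 27 gene lists had been fixed. Lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists so tested. An estimated correlation and the fry rotation test served as alternatives. With an estimated correlation, camera takes its p-values from the 3 residual degrees of freedom of the fit, so hardly any list can pass. Missing the threshold at that setting therefore says little for or against a list. The genes named are the targets Chd8 and Trp53; the 12 largest rises and 12 largest falls per comparison among genes past the threshold with at least 2 scaled TPM in the higher group and no overlap of libraries, predicted genes and pseudogenes passed over; up to 4 members of smallest p per list; 10 fixed erythroid and p53 genes; and the most abundant markers of other cell types. The same rule had been written for CPM and was applied to TPM. Genes named outside the rule are said to be so. Symbols were matched to the reference tables for chromosome, position and biotype (assembly GRCm38.p6): 95.5% of symbols were in the table of gene names and 82.5% in the RefSeq table, and 11636 tested genes had a chromosome.

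The fit was tested on simulated data made from the real means, with 200 of 12588 genes changed, in 5 runs per comparison. The changed genes were drawn from those with a mean of at least 2 scaled TPM, and noise was drawn independently for each gene. The recovery therefore does not cover lower genes or genes that vary together. For P53KO vs WT it recovered 83.8% of genes with a log2 change of 1 and 98% of those with a log2 change of 2, and 8.09% of its calls were false. For DKO vs P53KO the values were 81.8%, 98.4% and 4.85%, and for DKO vs WT 81.4%, 97% and 5.51%. Alternatives tried were other scalings (none, median of ratios, globin and mitochondrial genes removed, quantile normalization), other filters, a pseudocount of 0.1, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. For the overlap of comparisons, the group they share was also split, with 1 of its libraries in each comparison, an alternative chosen after the data had been seen. TPM values cannot separate reads of near-identical genes or of overlapping genes on opposite strands, so paralogs such as Hba-a1 and Hba-a2, and ribosomal protein genes with pseudogenes, are uncertain. Figures were drawn with matplotlib 3.10.9.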

Results

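Gene expression was profiled in sorted bone marrow proerythroblasts of 3 genotypes, to examine the part that the chromatin remodeller CHD8 plays in terminal erythropoiesis. p53 is the tumour suppressor transcription factor encoded by Trp53. By their labels, P53KO lacks p53 and DKO lacks Chd8 and p53, while WT carries floxed alleles of both genes and the P53KO label names no Chd8 allele. The P53KO libraries also differed from the others in Y-linked genes and in genes near Chd8, so the comparisons with P53KO hold those differences too. The libraries held between 10404 and 10919 genes above 1 TPM. Sequencing depth is unknown, since TPM does not keep it. Libraries of a group correlated at r = 0.9844 to 0.9863 across genes, which are not independent replicates, and libraries of different groups at 0.9412 to 0.9777. The first principal component held 59.8% of the variance and placed DKO 1 and DKO 2 at 57.4 and 49.5 and the other 4 libraries between -28.8 and -24.2. The second held 17.5% and placed the WT libraries at 26.7 and 22.3, P53KO at -22.0 and -25.7 and DKO at -9.58 and 8.39. Globin transcripts made up 9.15% and 7.19% of the TPM in DKO, 0.744% and 0.770% in WT and 0.534% and 0.477% in P53KO. Mitochondrially encoded transcripts made up 8.21% and 8.0% in P53KO, 2.66% and 3.25% in WT and 2.55% and 1.79% in DKO.

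The targeted genes were examined first. Trp53 (chromosome 11, 69580348 to 69591873, GRCm38) stood at 241 and 226 scaled TPM in the WT libraries, 9.3 and 10.5 in P53KO and 16.9 and 21.2 in DKO. It was lower in P53KO than in WT by a log2 fold change of -4.43 ± 0.13 (limma, adjusted p = 4.07e-05) and in DKO than in WT by -3.56 ± 0.13 (adjusted p = 0.000246). It was higher in DKO than in P53KO, by 0.88 ± 0.13 (adjusted p = 0.00384). Chd8 (chromosome 14, 52198151 to 52258042) stood at 49.7 and 50.4 in WT, 45.9 and 47.5 in P53KO and 36.8 and 33.5 in DKO. Its log2 fold change was -0.40 ± 0.09 in DKO vs P53KO (adjusted p = 0.0149), -0.50 ± 0.09 in DKO vs WT (adjusted p = 0.00672) and -0.10 ± 0.09 in P53KO vs WT (adjusted p = 0.654). The gene-level value covers all exons and the labels do not say which part is deleted, so most of the Chd8 message measured in DKO can come from outside that part. The share of Chd8 alleles deleted in these cells cannot be read from this value either, and the label is checked only in part. The Chd8 log2 fold change in DKO vs P53KO missed the threshold without P53KO 1 (adjusted p = 0.0521), without P53KO 2 (0.0701) and without DKO 2 (0.0671).

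**Figure D1:**
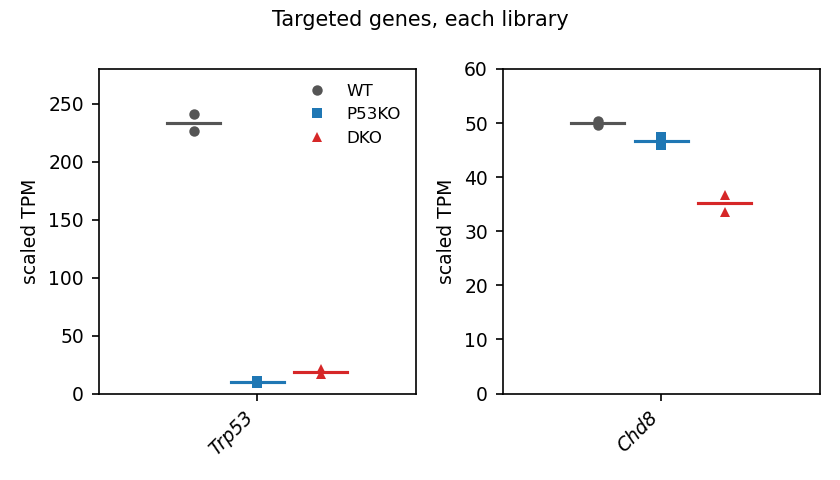
Scaled TPM (linear axis from 0) of Trp53 and Chd8 in each library of WT, P53KO and DKO; points are libraries and bars are the means of 2 libraries. Trp53 falls from 241 and 226 in WT to 9.3 and 10.5 in P53KO, and Chd8 is lowest in DKO, at 36.8 and 33.5.

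Few genes passed the threshold between P53KO and WT, which with 2 libraries per group does not show that few differed. In P53KO vs WT, 45 of 12588 genes passed the threshold, 20 higher and 25 lower, and 1660 had an unadjusted p under 0.05. The lower genes included 4 genes of the Y chromosome (Ddx3y, Eif2s3y, Kdm5d and Uty), near 0 in both P53KO libraries and present in WT and DKO. Eif2s3y, a translation initiation factor subunit, averaged 47.5 ± 1.9 scaled TPM in WT, 0.018 ± 0.001 in P53KO and 63.7 ± 4.8 in DKO. Its X-linked partner Eif2s3x was higher in P53KO than in WT, at 258 ± 17 against 151 ± 1 (log2 fold change 0.77 ± 0.08, adjusted p = 0.0212). Another 8 of the 45 genes lay within 20 Mb of Chd8 on chromosome 14. Of these, Ccnb1ip1 averaged 63.6 ± 12 in WT, 0.019 ± 0.027 in P53KO and 21.4 ± 5.9 in DKO. Pnp2 and Pnp, neighbouring genes for purine nucleoside phosphorylases, went the other way, at 39.7 ± 0.9 and 459 ± 13 in P53KO against 2.96 ± 0.09 and 148 ± 19 in WT, and at 1.86 ± 0.28 and 104 ± 9 in DKO. Ndrg2, Ppp1r3e and Fam124a were higher and Arhgef40 and Trav7n-6 lower in P53KO than in WT. The calls of Ccnb1ip1, Pnp2, Pnp, Eif2s3y, Ddx3y and Kdm5d held without any 1 library. Eif2s3x (adjusted p = 0.161, 0.156, 0.0559 and 0.105), Uty (0.136, 0.123, 0.0648 and 0.0734) and Ndrg2 (0.167, 0.171, 0.126 and 0.0776) missed the threshold without WT 1, WT 2, P53KO 1 or P53KO 2. Fam124a missed it without WT 1 or WT 2 (0.145 and 0.123), Ppp1r3e without WT 2 (0.0581), Trav7n-6 without P53KO 1 or P53KO 2 (0.119 and 0.112), and Arhgef40 without WT 1, WT 2, P53KO 1, DKO 1 or DKO 2 (0.277, 0.276, 0.0559, 0.0612 and 0.0585). Tested genes within 20 Mb of Chd8 passed more often than genes elsewhere (3.79% against 0.123%; Fisher's exact test, two-sided, odds ratio 32, p = 3.03e-09, 8 of 211 genes near Chd8 and 21 called of 10806 tested genes with a RefSeq position, pseudogenes left out; this test was chosen after the values were seen).

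**Figure D2:**
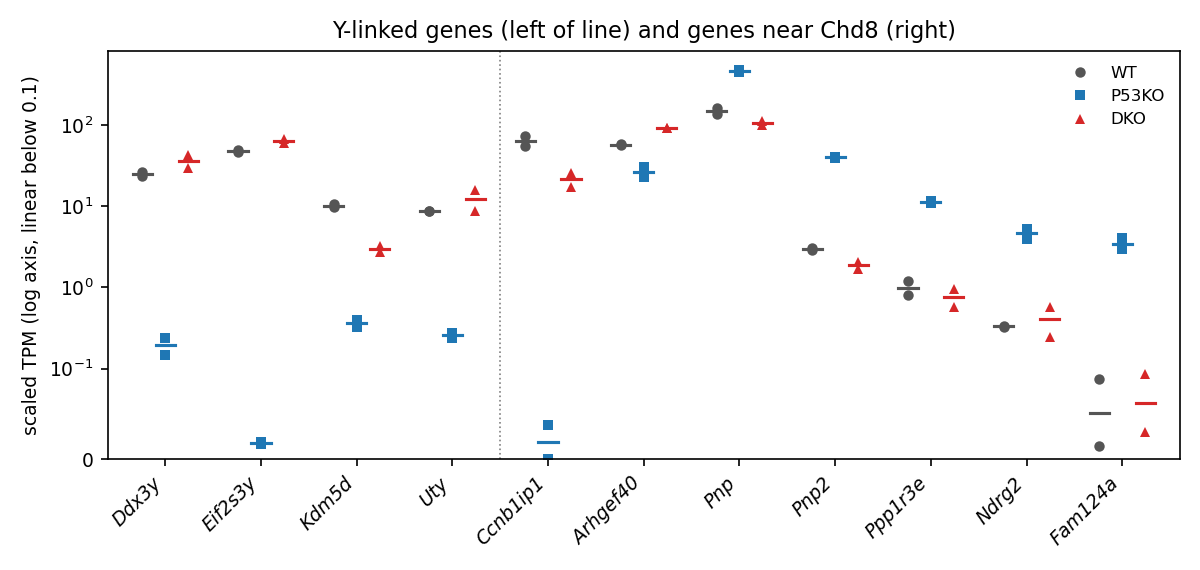
Scaled TPM of Y-linked genes and of genes within 20 Mb of Chd8 in each library (log axis, linear below 0.1); points are libraries and bars are group means. Eif2s3y and Ccnb1ip1 average 0.018 and 0.019 in P53KO against 47.5 and 63.6 in WT, while Pnp2 averages 39.7 in P53KO against 2.96 in WT.

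Of the 13 mitochondrially encoded genes, 4 passed in P53KO vs WT, all higher in P53KO. Adjusted over these genes alone, a list chosen after the data were seen, 12 were higher. mt-Atp8 averaged 18430 ± 1250 scaled TPM in P53KO against 2207 ± 428 in WT (log2 fold change 3.07 ± 0.33, adjusted p = 0.0241), and mt-Co3, mt-Nd1 and mt-Nd2 had log2 fold changes of 2.13 ± 0.27, 1.29 ± 0.17 and 1.56 ± 0.18. All 4 missed the threshold without WT 1, WT 2, P53KO 1 or P53KO 2 (adjusted p = 0.171, 0.131, 0.124 and 0.105 for mt-Atp8, and from 0.11 to 0.263 for the others). A nuclear copy of mitochondrial DNA, Gm10925, named after its values were seen, was also higher. The other calls were 16 pseudogenes or predicted genes and 12 further genes. The last included Rpl34, Sat2 and Il3ra. Rpl34 stood at 2032 ± 84 in P53KO and 353 ± 24 in WT. Its pseudogenes Rpl34-ps1 and Rpl34-ps2, named after their values were seen, were lower, so that the share of reads of Rpl34 is uncertain. Sat2, which lies near Trp53, stood at 8.46 ± 1.7 in P53KO, 0.247 ± 0.14 in WT and 4.36 ± 1.3 in DKO. Il3ra, the alpha chain of the interleukin 3 receptor, stood at 1.04 ± 0.15, 6.79 ± 0.30 and 1.98 ± 0.02. Within 20 Mb of Trp53, 2 of 402 tested genes passed (Fisher's exact test, two-sided, odds ratio 2.73, p = 0.183). Il3ra missed the threshold without WT 1, WT 2, P53KO 1 or P53KO 2 (adjusted p = 0.102, 0.11, 0.0573 and 0.0542), and Sat2 without WT 1, WT 2 or P53KO 1 (0.0862, 0.0719 and 0.0529).

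Genes of the p53 pathway were lower in P53KO as a list. The 23 tested p53 target genes had a median log2 fold change of -0.26 in P53KO vs WT (camera, adjusted p = 0.000536), which did not pass with an estimated correlation (adjusted p = 0.506); fry gave 0.0453. None of the 23 passed over all genes tested, 6 were lower adjusted over the list alone, and 7 had an unadjusted p under 0.05. Bbc3 (PUMA, a pro-apoptotic p53 target) stood at 2.49 ± 0.19 in P53KO against 6.26 ± 0.36 in WT (adjusted p = 0.0941), Ccng1 at 26.2 ± 2.1 against 38.4 ± 0.9 (adjusted p = 0.167), and Zmat3 at 1.29 ± 0.39 against 3.39 ± 0.13 (adjusted p = 0.18). Cdkn1a, the cell cycle inhibitor p21, was low throughout, at 1.29 ± 0.65 in WT and 0.176 ± 0.004 in P53KO (adjusted p = 0.266). Mdm2, a p53 target that encodes its inhibitor, stood at 37.0 ± 5.0 in P53KO and 35.0 ± 0.7 in WT (adjusted p = 0.809).

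Neutrophil and monocyte markers formed the other list past the threshold in P53KO vs WT (20 tested, median log2 fold change -1.13, camera adjusted p = 0.000536; adjusted p = 0.891 with an estimated correlation and 0.681 with fry). None of the 20 passed alone or adjusted over the list alone, and 2 had an unadjusted p under 0.05. These genes differed widely within groups: S100a9 stood at 402 and 99.1 scaled TPM in the WT libraries, 121 and 12.2 in P53KO and 391 and 551 in DKO. The list missed the threshold without WT 1 (median -0.61, adjusted p = 0.116) and without P53KO 2 (median -0.52, adjusted p = 0.351). The other 23 lists had adjusted p-values from 0.0511 for B cell markers to 0.889 for Epo and STAT5 signalling. Red cell lists were among them. Alas2 stood at 34.9 ± 8.8 in P53KO and 37.6 ± 3.2 in WT, Gata1 at 252 ± 5 and 260 ± 34, and Kit at 54.0 ± 8.8 and 47.9 ± 1.9. Of 7 globin genes 0 passed over all genes tested with limma, 2 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone (camera, adjusted p = 0.609). Hbb-bs stood at 1515 ± 629 in P53KO and 2779 ± 75 in WT (adjusted p = 0.259) and Hba-a2 at 1098 ± 51 and 1689 ± 74 (adjusted p = 0.225). The number of genes past the threshold in P53KO vs WT depended on the libraries: it was 23 without WT 1 or without WT 2, 82 without DKO 1, 83 without DKO 2, and 87 in a fit of the 4 libraries compared. With no filter on low values it was 26.

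Many genes differed between DKO and P53KO. In DKO vs P53KO, 4721 genes (37.5%) passed, 2306 higher and 2415 lower in DKO; 724 rose and 705 fell by at least 2-fold. Genes of hemoglobin production and the red cell membrane rose: Hbb-bs, an adult beta-globin, averaged 35170 ± 1200 scaled TPM in DKO against 1515 ± 629 in P53KO (log2 fold change 4.60 ± 0.26, adjusted p = 0.000313), and Alas2, the first enzyme of erythroid heme synthesis, 531 ± 111 against 34.9 ± 8.8 (3.89 ± 0.20, adjusted p = 0.000243). Kit, the stem cell factor receptor of early progenitors, fell from 54.0 ± 8.8 to 12.4 ± 3.5 (-2.05 ± 0.20, adjusted p = 0.00107). Myb, a transcription factor of immature cells, fell from 117 ± 16 to 24.5 ± 8.1 (-2.24 ± 0.21, adjusted p = 0.00107). Neutrophil markers and Y-linked genes were higher in DKO than in P53KO too, as given with the markers of other cells and the largest changes. The count was 3089 without P53KO 1, 3108 without P53KO 2 and 3136 without DKO 1.

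**Figure D3:**
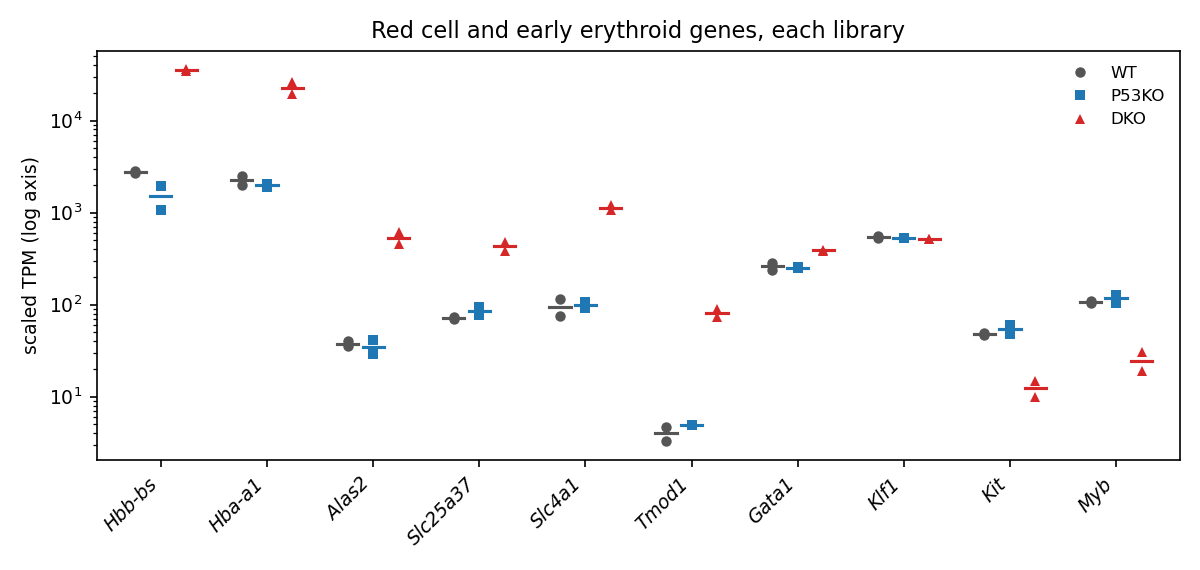
Scaled TPM (log axis) of red cell genes and early erythroid genes in each library of WT, P53KO and DKO; points are libraries and bars are group means. Hbb-bs averages 35170 in DKO against 2779 in WT and 1515 in P53KO, Klf1 means lie between 514 and 544, and Kit and Myb are lowest in DKO.

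The red cell lists rose together. With fry, which does not compare a list with other genes, adjusted p in DKO vs P53KO was 0.00341 for the membrane and skeleton list. It was 0.00779 for globins, 0.0116 for heme and iron, 0.00622 for maturation and 0.01815 for the erythroid transcription factors. Of the 21 genes of the red cell membrane and skeleton, 16 rose and 0 fell (17 rose adjusted over the list alone), with a median log2 fold change of 1.10 (camera, adjusted p = 1.69e-07; adjusted p = 0.532 with an estimated correlation). Tmod1, which caps actin in the membrane skeleton, averaged 81.4 ± 10 in DKO against 4.90 ± 0.03 in P53KO. Epb42 (protein 4.2), Spta1 (alpha-spectrin) and Gypc (glycophorin C) had log2 fold changes of 1.83 ± 0.08, 1.80 ± 0.10 and 1.45 ± 0.07. Of 7 tested globin genes 6 rose (median 2.94, adjusted p = 0.00287; adjusted p = 0.593 with an estimated correlation). Hba-a1 and Hba-a2, near-identical copies whose reads cannot be told apart with certainty, averaged 22760 ± 4580 and 20960 ± 4410 in DKO, and the embryonic beta-like gene Hbb-bh1 stood at 1.26 ± 0.49 against 0.122 ± 0.17 in P53KO, a call lost without P53KO 2 (adjusted p = 0.0914). Of 17 genes of heme synthesis and iron uptake, 13 rose and 2 fell (median 0.68, adjusted p = 0.00195; adjusted p = 0.593 with an estimated correlation). The mitochondrial iron importer Slc25a37 rose by 2.30 ± 0.14 and the heme enzyme Alad by 1.5 ± 0.09, whereas the ferrireductase Steap3 fell by 1.36 ± 0.11. The transferrin receptor Tfrc rose from 398 ± 67 to 727 ± 170 (adjusted p = 0.012), a call lost without P53KO 1 (adjusted p = 0.0558). Of 16 genes of terminal maturation, mitophagy and enucleation, 14 rose and 1 fell (median 0.87, adjusted p = 0.000105; adjusted p = 0.532 with an estimated correlation). They included the ubiquitin-conjugating enzymes Ube2l6 (1.66 ± 0.08) and Ube2o (1.26 ± 0.10) and the autophagy gene Map1lc3b (0.91 ± 0.10).

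Among 16 erythroid transcription factors 9 rose and 1 fell in DKO vs P53KO (median 0.51, adjusted p = 0.00925; adjusted p = 0.593 with an estimated correlation), and 9 rose and 2 fell adjusted over the list alone. Sox6 rose from 16.5 ± 1.9 to 80.9 ± 13, and Gata1, Tal1, Nfe2 and Zfpm1 rose by 0.63 ± 0.10, 0.74 ± 0.09, 1.08 ± 0.13 and 1.04 ± 0.07. Klf1 stood at 514 ± 4 in DKO and 532 ± 3 in P53KO (log2 fold change -0.05 ± 0.07, adjusted p = 0.597). Of 15 genes of Epo and STAT5 signalling 7 rose and 3 fell, and 10 rose and 3 fell adjusted over the list alone; the list missed the threshold (median 1.42, camera adjusted p = 0.0926; fry 0.0451). The feedback inhibitor Socs2 rose from 1.53 ± 0.49 to 20.7 ± 2.6 and the anti-apoptotic Bcl2l1 from 9.31 ± 0.89 to 32.4 ± 3.6, while Stat5a fell from 73.6 ± 2.0 to 26.8 ± 4.3 and the phosphatase gene Ptpn6 from 71.8 ± 12 to 26.2 ± 4.3. The 11 tested stem and early progenitor genes moved both ways, 3 up and 2 down (median 0.46, adjusted p = 0.173): Kit and Myb fell, while Lyl1 and Spi1 rose, the latter to 3.53 ± 0.32 scaled TPM.

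Some cell division genes rose as well in DKO vs P53KO, where their lists passed only with camera at the preset correlation. In DKO vs P53KO, 9 of 18 G2/M genes rose (median 0.46, adjusted p = 0.00117), 8 of 17 cytokinesis genes (median 0.40, adjusted p = 0.00277) and 12 of 25 genes of DNA replication, of which 1 fell (median 0.29, adjusted p = 0.00767). Each had adjusted p = 0.593 with an estimated correlation, and fry gave 0.0629, 0.057 and 0.0607. Adjusted over the list alone, 13, 9 and 13 genes rose and 0, 0 and 2 fell. Kif23, a motor protein of the midbody, rose from 86.7 ± 14 to 194 ± 2, Mki67 from 292 ± 35 to 558 ± 15, and the histone mRNA binding protein gene Slbp from 303 ± 7 to 560 ± 11. The list of Rho family GTPases and regulators was lower (29 tested, 8 down and 2 up, median -0.22, adjusted p = 0.0363; adjusted p = 0.532 with an estimated correlation). Arhgdia, Nckap1l and Was, regulators of Rho GTPases and actin, fell by 1.44 ± 0.08, 1.29 ± 0.13 and 1.18 ± 0.11, whereas Arhgdib, a second Rho GDP dissociation inhibitor, rose by 2.49 ± 0.21. The Rho list missed the threshold without DKO 2 (adjusted p = 0.0971) and with a filter of 1 TPM (adjusted p = 0.0588).

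Some stress and interferon genes rose in DKO vs P53KO, and most members of both lists did not pass. Of 18 genes of the integrated stress and unfolded protein response 5 rose and 1 fell (median 0.36, adjusted p = 0.0188; adjusted p = 0.593 with an estimated correlation). Ddit3 (CHOP) rose from 47.9 ± 0.4 to 170 ± 12, its activator Atf4 from 277 ± 44 to 546 ± 20 and Trib3 from 0.310 ± 0.019 to 19.4 ± 3.6, while the asparagine synthetase gene Asns fell from 286 ± 30 to 194 ± 1. The list missed the threshold without P53KO 1, where its median fell to 0.12, and without DKO 1, where its median was 0.29. Of 25 interferon response genes 7 rose and 0 fell (6 rose adjusted over the list alone; median 0.44, adjusted p = 0.00362; adjusted p = 0.593 with an estimated correlation, 0.0629 with fry). Rsad2 (viperin) rose from 3.72 ± 2.2 to 37.5 ± 1.0 and Isg15 from 14.3 ± 6.2 to 76.5 ± 5.7. All groups had received pI:pC, a synthetic double-stranded RNA that induces interferon. Nuclear genes of oxidative phosphorylation were close to the threshold (27 tested, 8 up and 1 down, median 0.20, adjusted p = 0.0473; adjusted p = 0.593 with an estimated correlation), and the list missed it in 9 alternatives, among them TPM as deposited (adjusted p = 0.0628) and the fits without P53KO 1 (adjusted p = 0.162), WT 1 (0.0571), WT 2 (0.0559) or DKO 2 (0.0797).

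p53 target genes moved both ways in DKO vs P53KO, where both groups are labelled as p53-deleted. Of 23, 6 rose and 3 fell (median 0.17, camera adjusted p = 0.308, and fry, upward, adjusted p = 0.0109). Trp53 itself was higher in DKO (16.9 and 21.2 scaled TPM) than in P53KO (9.3 and 10.5). The gene-level value does not show how complete the deletion was, so remaining p53 in DKO was not excluded. Bbc3 rose from 2.49 ± 0.19 to 15.2 ± 2.4 and Btg2, an antiproliferative gene, from 10.8 ± 1.0 to 59.2 ± 5.8, while Ccng1 fell from 26.2 ± 2.1 to 14.2 ± 0.3. Cdkn1a rose from 0.176 ± 0.004 to 1.84 ± 0.57 (adjusted p = 0.0125), a call lost without P53KO 1 (adjusted p = 0.0518), without P53KO 2 (0.0517) and without DKO 1 (0.0705). Mdm2 rose from 37.0 ± 5.0 to 54.5 ± 3.3 (adjusted p = 0.0124), a call lost without P53KO 1 (0.0544) and without DKO 1 (0.0573). Of 16 apoptosis regulators 6 fell and 2 rose (median -0.09, camera adjusted p = 0.21; fry 0.0404). The executioner caspase Casp3 fell from 259 ± 48 to 47.7 ± 4.6, and the pro-apoptotic Bid, Bcl2l11 and Bad fell by 1.59 ± 0.08, 1.32 ± 0.16 and 0.76 ± 0.11. Among the 7 other CHD genes tested, Chd3 and Chd4 fell by 2.58 ± 0.27 and 0.68 ± 0.08 and Chd2 and Chd7 rose by 0.74 ± 0.11 and 1.03 ± 0.18 (list adjusted p = 0.786). Of 79 cytosolic ribosomal protein genes 26 fell and 14 rose (26 and 17 adjusted over the list alone; list adjusted p = 0.208), Rps4x from 2774 ± 56 to 1068 ± 10. Of 24 ribosome biogenesis genes 6 fell and 0 rose (4 fell adjusted over the list alone; list adjusted p = 0.0716). The Wnt list (1 of 7 rose, 0 adjusted over the list alone, median -0.32) and the immediate early list (2 of 12 rose) had adjusted p-values of 0.347 and 0.308. For the fixed lists whose count in DKO vs P53KO is given once, the count adjusted over the list alone was equal.

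Markers of other blood cells also differed between DKO and P53KO. Of 20 neutrophil and monocyte markers 10 rose and 0 fell (14 rose adjusted over the list alone; median 2.05, adjusted p = 0.00287; adjusted p = 0.593 with an estimated correlation, 0.183 with fry). Camp, S100a9, Ngp and Ltf, granule or cytosolic proteins of neutrophils, passed with all 6 libraries and missed the threshold without P53KO 2, without DKO 1 and without DKO 2 (adjusted p = 0.0541, 0.071 and 0.0957 for Camp, and from 0.0776 to 0.133 for the others). S100a9 averaged 471 ± 113 in DKO, 66.6 ± 77 in P53KO and 250 ± 214 in WT. Of 10 B cell markers 4 rose (median 0.93, adjusted p = 0.00767; adjusted p = 0.593 with an estimated correlation), a list call lost without DKO 2 (adjusted p = 0.0708); Vpreb1, the surrogate light chain of B cell precursors, stood at 6.77 ± 2.8 in DKO and 0.742 ± 0.29 in P53KO. Of 8 megakaryocyte and platelet markers 5 rose and 1 fell (median 0.76, adjusted p = 0.0275; adjusted p = 0.532 with an estimated correlation), among them Itga2b (CD41, 11.6 ± 3.3 against 1.59 ± 0.26), while Gp5 fell from 11.3 ± 0.2 to 3.52 ± 0.98. The call of that list was lost without DKO 1 (adjusted p = 0.106), without DKO 2 (0.148) and with a filter of 1 TPM (0.145). Of 9 macrophage markers 2 rose and 1 fell (list adjusted p = 0.164). In this list the iron exporter Slc40a1, which erythroid cells also express, fell from 130 ± 12 to 63.7 ± 8.1. The T and NK cell list and the mast cell and basophil list had 3 tested members each and no list test. Lck, a kinase of T cells, stood at 14.1 ± 2.2 in DKO, 4.75 ± 1.1 in P53KO and 1.40 ± 0.60 in WT. Other T cell genes were low: Cd3e, Cd3g, Trac and Trbc2 averaged 0.066, 0.057, 0.032 and 0.095 TPM as deposited over all libraries. Cd3d stood at 0.686 in DKO and 0.642 in P53KO, and Nkg7 at 1.03 and 0.193. Lck alone does not show T cells. The basophil proteases Mcpt8 and Prss34 were listed at 0 in both DKO libraries and in P53KO 2, and averaged 1.43 and 0.574 in WT. Hdc, the other tested member, stood at 1.02 in DKO and 0.219 in P53KO.

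**Figure D4:**
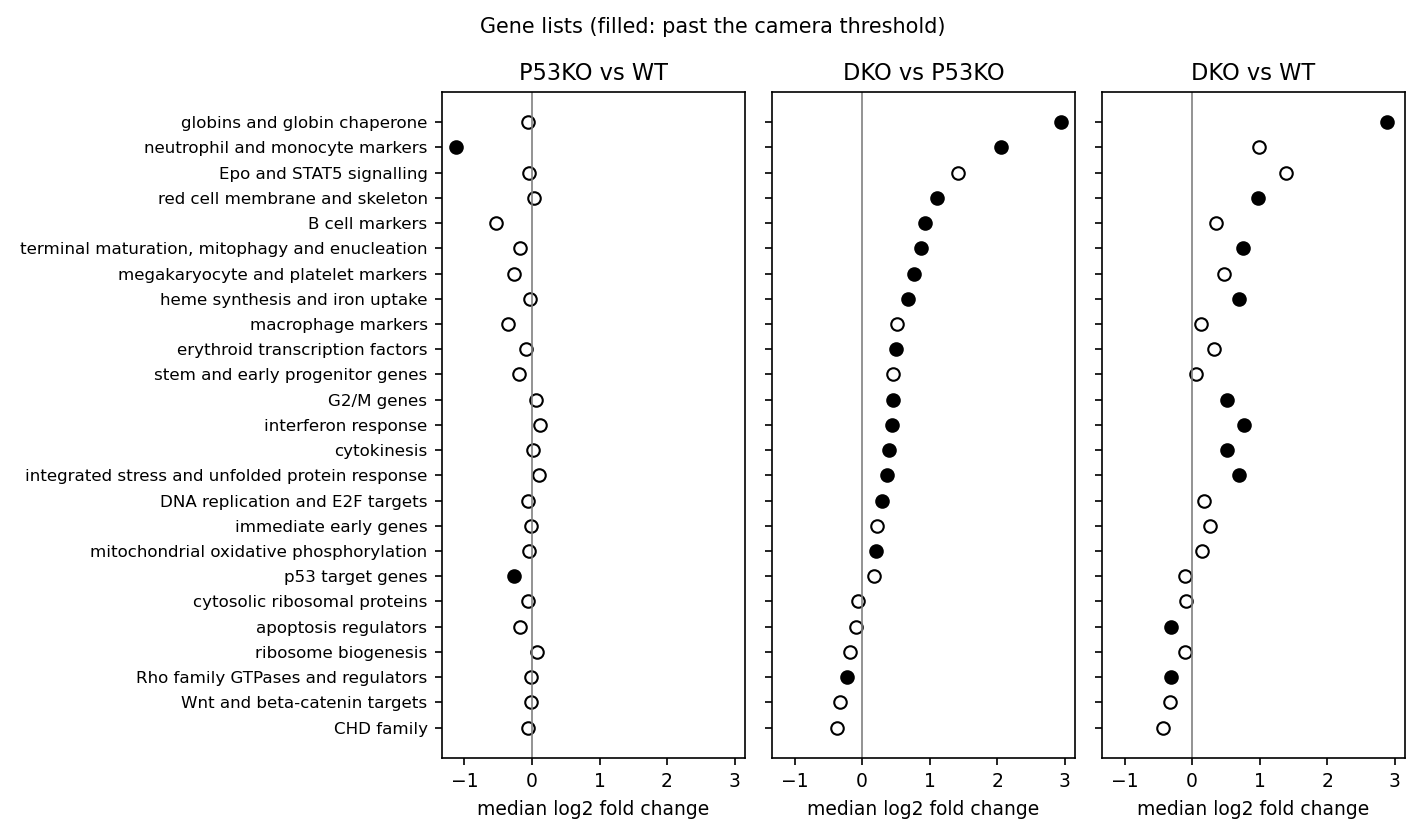
Median log2 fold change (horizontal axis) of each fixed gene list with at least 5 tested members, for P53KO vs WT, DKO vs P53KO and DKO vs WT; filled points passed the camera threshold at the preset correlation and open points did not. The globin list has the highest median in both DKO comparisons, 2.94 and 2.89, and 2 lists pass in P53KO vs WT.

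The genes of largest change in DKO vs P53KO were outside the lists in part. Gmpr, a GMP reductase, rose from 0.554 ± 0.020 to 116 ± 75 scaled TPM (log2 fold change 6.06 ± 0.43, adjusted p = 0.000453), Cda, cytidine deaminase, from 1.52 ± 0.15 to 64.9 ± 10, and C2cd4a from 2.32 ± 0.04 to 60.6 ± 7.3. Among the falls, Spon2, an extracellular matrix protein gene, went from 29.6 ± 1.0 to 0.385 ± 0.13 (-4.47 ± 0.20), Zfp512b from 28.8 ± 3.1 to 0.910 ± 0.044, the actin-binding Cnn3 from 64.5 ± 19 to 2.48 ± 1.2, and the acyl-CoA synthetase Acsl6 from 29.9 ± 1.4 to 1.31 ± 0.61. Eif2s3y, Ddx3y and Ccnb1ip1 were among the largest rises and Pnp2 among the largest falls, in each case with WT nearer to DKO than to P53KO.

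The comparison of DKO with WT was similar in size. In DKO vs WT, 4857 genes (38.6%) passed, 2310 higher and 2547 lower; with TPM as deposited, without composition factors, 36.5% of the genes past the threshold were higher, against 47.6%. At least 2-fold changes numbered 618 up and 829 down. The count was 3025 without WT 1 and 2953 without DKO 1. Red cell genes were again higher in DKO: Hbb-bs 35170 ± 1200 against 2779 ± 75 in WT (log2 fold change 3.66 ± 0.26, adjusted p = 0.000455), Alas2 531 ± 111 against 37.6 ± 3.2 (3.77 ± 0.20, adjusted p = 0.000315), and Slc4a1, the band 3 anion exchanger, 1127 ± 97 against 94.8 ± 28 (3.59 ± 0.19, adjusted p = 0.000315). Kit and Myb were lower, by -1.90 ± 0.20 and -2.12 ± 0.21. The largest rises also held Gmpr, Cda, C2cd4a, Plek2 (94.0 ± 21 against 2.78 ± 1.2) and the fatty acid binding protein gene Fabp5 (657 ± 140 against 42.2 ± 5.5), and the largest falls held Spon2, Zfp512b, Cnn3, Acsl6 and Shank3 (2.24 ± 0.71 against 31.1 ± 0.1).

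In DKO vs WT, 16 of 21 red cell membrane genes rose (median 0.98, adjusted p = 1.53e-07), 6 of 7 globins (median 2.89, adjusted p = 0.00104), 12 of 17 heme and iron genes with 2 lower (median 0.69, adjusted p = 0.000741), and 11 of 16 maturation genes with 1 lower (median 0.75, adjusted p = 0.000755). G2/M genes (13 of 18 up, adjusted p = 0.000288), cytokinesis genes (11 of 17 up, adjusted p = 0.000741), stress response genes (7 up and 1 down of 18, adjusted p = 0.00323) and interferon genes (10 up and 1 down of 25, adjusted p = 0.0022) also rose as lists. Apoptosis regulators (7 down and 2 up of 16, median -0.32, adjusted p = 0.0283) and the Rho list (13 down and 5 up of 29, median -0.32, adjusted p = 0.0478) were lower. Adjusted over the list alone, the counts up and down were 17 and 0 for the membrane, 14 and 2 for heme and iron, 14 and 0 for G2/M, 13 and 0 for cytokinesis, 8 and 1 for stress, 13 and 2 for interferon and 6 and 15 for Rho genes, and equal to those given for the other 3 lists. Each of these 10 list calls had adjusted p = 0.664 with camera at an estimated correlation. All 10 passed in the same direction with fry, which passed 17 of the 25 lists in this comparison. The apoptosis call was lost without DKO 1 (adjusted p = 0.0583), the interferon call without DKO 2 (adjusted p = 0.0525), and the Rho call under 7 alternatives, among them without WT 1 (0.0593), P53KO 1 (0.0601), P53KO 2 (0.061) or DKO 2 (0.136). Casp3 averaged 47.7 ± 4.6 in DKO and 217 ± 6 in WT, and Isg15 76.5 ± 5.7 and 12.8 ± 3.0. The remaining lists missed the threshold, the closest being DNA replication (10 up and 2 down of 25, adjusted p = 0.0522) and erythroid transcription factors (8 up and 1 down of 16, adjusted p = 0.0735). p53 target genes were split, 5 up and 5 down of 23 (adjusted p = 0.7): Ccng1 stood at 14.2 ± 0.3 in DKO and 38.4 ± 0.9 in WT, and Btg2 at 59.2 ± 5.8 and 12.8 ± 2.3. Neutrophil markers had adjusted p = 0.232, with Fcnb and Prtn3 higher and Retnlg lower in DKO (1 up and 0 down adjusted over the list alone). Prtn3 missed the threshold without WT 1, WT 2 or DKO 2 (adjusted p = 0.0517, 0.136 and 0.0917), Retnlg without WT 1, DKO 1 or DKO 2 (0.195, 0.148 and 0.0998), and both Fcnb and Retnlg with a pseudocount of 0.1 (0.0568 and 0.0516).

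The comparisons share libraries, so their overlap was set beside chance values. Of the genes past the threshold, 3710 passed in the same direction in DKO vs P53KO and DKO vs WT and 12 in opposite directions. Independent lists of these sizes would share 911.8. With all 6 libraries simulated from the same means, without change between groups, 0.2 genes were shared on average over 20 draws. Hardly any gene can pass in such draws, so that count does not measure overlap caused by the shared DKO libraries. Fold changes of the 2 comparisons correlated at r = 0.829 across genes (0.498 simulated), with a covariance of 0.463 against 0.0277 simulated. For P53KO vs WT and DKO vs P53KO, 1 gene passed in the same direction and 38 in opposite directions (r = -0.339 against -0.505 simulated; covariance -0.113 against -0.0282). For P53KO vs WT and DKO vs WT, 19 passed in the same direction and 8 in opposite directions, with 8.73 from independent lists (r = 0.245 against 0.497 simulated; covariance 0.0789 against 0.0276). With 1 library of the shared group in each comparison, in both ways, DKO vs P53KO and DKO vs WT had 2378 and 2187 genes in the same direction and 15 and 60 in opposite directions, where independent lists would share 416.1 and 502.1 (r = 0.762 and 0.646). P53KO vs WT and DKO vs P53KO then had 23 and 22 genes in opposite directions and 3 and 8 in the same direction (r = -0.191 and -0.17). P53KO vs WT and DKO vs WT had 9 and 7 in the same direction and 4 and 2 in opposite directions, with 2.87 and 3.06 from independent lists (r = 0.0883 and 0.119). With an estimated correlation, 0 lists passed in any comparison (1 list per comparison had an unadjusted p under 0.05), while fry, which tests whether a list moves without comparing it with other genes, gave 1, 12 and 17 lists.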

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

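The filter and pseudocount for TPM, the scalings, the block and the left-out libraries were set before the data were examined; quantile normalization, the count without special gene classes and the split of shared groups were chosen after. The count-based tests planned as alternatives were not run, since they need read counts. For genes changed in P53KO vs WT the count of 45 became 26 with no filter (genes higher in P53KO vs WT 8), 87 in a fit of the 4 libraries compared (47 higher; genes lower in P53KO vs WT 40), and 12 (5 higher, 7 lower) without Y-linked genes, genes near Chd8, mitochondrial genes with their copies, and pseudogenes. Leaving out 1 library at a time, the lone library taken to vary like the other groups, gave 23 to 83 genes (7 to 46 higher, 14 to 37 lower). In the same way genes changed in DKO vs P53KO ranged from 3089 to 4336 (genes higher in DKO vs P53KO 1484 to 2154, genes lower in DKO vs P53KO 1605 to 2182) and genes changed in DKO vs WT from 2953 to 4600 (genes higher in DKO vs WT 1399 to 2162, genes lower in DKO vs WT 1554 to 2438), and the Chd8 log2 fold change in DKO vs P53KO from -0.45 to -0.33. Fewer libraries leave fewer degrees of freedom; otherwise the cause was not tested. The replicate numbers do not pair the samples (deviations of same-numbered libraries correlated at 0.0422, -0.0545 and 0.0117), and with the replicate block 32, 4299 and 4420 genes passed in P53KO vs WT, DKO vs P53KO and DKO vs WT, with 10 higher in P53KO vs WT. TPM as deposited moved the median log2 fold change of all genes to -0.101 in P53KO vs WT and -0.0776 in DKO vs WT, from -0.0267 and 0.0123. All genes called in the DKO comparisons and tested kept their sign with median-of-ratios scaling, TPM as deposited, and globin and mitochondrial genes removed; quantile normalization was run for counts and not for signs. Of the genes named by rule, 41 calls ended with no filter and 10 with a pseudocount of 0.1; the cause was not tested. A filter of 1 TPM, a pseudocount of 0.1, median-of-ratios scaling and quantile normalization kept each count within 1.5 times, and no gene or list named here changed direction past the threshold. Depth is unknown, so what it limits cannot be stated.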

Other observations

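The gene groups of this and the next paragraph, and all tests below except the removal of globin genes, were chosen after the data had been seen. Some cholesterol and fatty acid synthesis genes were lower in DKO. Of 24 tested, 10 fell and 1 rose in DKO vs P53KO, and 11 fell and 2 rose adjusted over the list alone. The list had a median log2 fold change of -0.28 there (camera adjusted p = 0.00776 over 4 added lists, 0.257 with an estimated correlation and 0.0114 with fry). In DKO vs WT 11 fell, also adjusted over the list alone (camera adjusted p = 0.00859, and 0.373 with an estimated correlation). Dhcr24, the last reductase of cholesterol synthesis, averaged 22.2 ± 4.6 scaled TPM in WT, 8.34 ± 0.05 in P53KO and 2.17 ± 0.18 in DKO, and the desaturase gene Scd2 41.0 ± 8.7, 32.9 ± 4.2 and 10.5 ± 1.6. Members did not all move this way: Fdft1, squalene synthase, stood at 13.3 ± 0.9 in DKO and 9.03 ± 1.2 in P53KO (log2 fold change 0.51, adjusted p = 0.0368). Some replication-dependent histone genes were higher in DKO. In DKO vs P53KO 20 of 64 rose and 0 fell (19 rose adjusted over the list alone, median 0.80, camera adjusted p = 5.73e-08, and 0.257 with an estimated correlation). Hist1h2bc rose from 21.8 to 99.3 ± 11 and Hist1h1c from 11.3 to 46.7 ± 0.8. In DKO vs WT 18 rose and 0 fell (16 rose adjusted over the list alone, camera adjusted p = 5.76e-06, and 0.373 with an estimated correlation).

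Eosinophil markers differed from WT as a list. All 6 were higher in WT 1 than in WT 2 and in P53KO 1 than in P53KO 2, as neutrophil markers were. The parallel did not extend to DKO. There 5 of 6 were higher in DKO 1, while neutrophil markers had a median ratio of 0.674 for DKO 1 over DKO 2. In P53KO vs WT the list had a median of -1.51 (camera adjusted p = 0.00243; adjusted p = 0.501 with an estimated correlation, 0.301 with fry), with 0 of 6 past the threshold in limma, 4 adjusted over the list alone and 4 at an unadjusted p under 0.05; Ear1 stood at 6.57 and 0.143 in P53KO and 1.79 and 0.799 in WT. In DKO vs WT 5 of 6 fell (median -2.13, adjusted p = 0.0136; adjusted p = 0.455 with an estimated correlation, 0.0906 with fry), and in DKO vs P53KO the list missed the threshold (median -0.66, adjusted p = 0.327). Prg2, the eosinophil granule major basic protein, averaged 64.5 ± 40 in WT, 9.86 ± 12 in P53KO and 1.41 ± 1.8 in DKO, and its fall in DKO vs WT was lost without WT 1 (adjusted p = 0.0749) and without DKO 2 (adjusted p = 0.0535). Of the 13 mitochondrially encoded genes, 12 fell in DKO vs P53KO (median -1.83) and 3 fell in DKO vs WT (1 adjusted over the list alone, median -0.47). The list was higher in P53KO vs WT (median 1.35, camera adjusted p = 2.68e-16, and 0.259 with an estimated correlation).

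Of the 45 genes past the threshold in P53KO vs WT, 4 were Y-linked, 8 lay near Chd8, 4 were mitochondrially encoded and 1 was a nuclear copy. For the Y-linked part, mice of another sex in the P53KO group are a candidate source: no Y-linked gene with a WT mean of at least 1 TPM, predicted and pseudogene models left out, exceeded 3.94% of its WT mean in P53KO, while in 3 predicted or pseudogene models (Gm21244, Gm8502 and Mid1-ps1) the higher P53KO library reached 74.1% to 99.2% of the WT mean and, for Mid1-ps1, the other was at 0. For the 8 genes near Chd8, another haplotype around Chd8 in the P53KO mice, whose genotype label names no Chd8 allele, remains open (odds ratio 32). For the mitochondrial part, an exchange of reads between mitochondrial genes and nuclear copies is argued against, since the summed TPM of both classes was higher in P53KO by 1.42 on the log2 scale. An effect of p53 loss that is the same with and without Chd8 is argued against only for the genes that moved back in DKO, labelled p53-deleted too. Some moved back in part: Ccnb1ip1 and Kdm5d averaged 21.4 and 2.99 in DKO against 63.6 and 10.05 in WT. Of the 45 genes, 19 passed in the same direction in DKO vs WT and 8 in the opposite direction. In DKO vs P53KO, 6 of 10 tested Y-linked genes rose and 12 of 13 mitochondrially encoded genes fell. Of the 8 genes near Chd8, Ccnb1ip1 and Arhgef40 were higher and Pnp, Pnp2, Ndrg2, Ppp1r3e and Fam124a lower in DKO than in P53KO. Trav7n-6 stayed low, at 0.007 in DKO. An effect of p53 in P53KO that is absent from DKO was not tested. The floxed Chd8 allele in the WT label, and any difference in sex, which the labels do not give, would be confounded with it.

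For the rise of red cell genes in DKO vs P53KO, a larger globin share of the TPM total is argued against: it would shift other genes by -0.13 on the log2 scale, while the red cell membrane and skeleton list had a median of 1.08 in TPM as deposited. Removing globin and mitochondrial genes moved this median little, to 1.10, and decides nothing. Sex or Chd8-linked haplotype of the P53KO mice is also argued against, since the list had a median of 0.976 against WT, which expresses the Y-linked genes. More mature cells, or their RNA, in the DKO sorts cannot be told apart from a change within proerythroblasts: Kit and Myb fell, yet 3 members of the stem and early progenitor list rose, and no measure of the sorted cells' stage was used here. An effect of Chd8 loss itself was not tested apart from this.

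Neutrophil genes varied between libraries of a group. Unequal carry-over of neutrophil-lineage cells, or of their RNA, may account for the spread within WT and P53KO: all 13 markers with a mean of at least 5 TPM were higher in WT 1 than in WT 2 and in P53KO 1 than in P53KO 2 (median ratios 3.76 and 9.91; 0.674 for DKO 1 over DKO 2). The most abundant, S100a9, reached 402 in WT 1 and 551 scaled TPM in DKO 2, although the cells had been sorted as proerythroblasts. The same kind of carried-over cells in WT and DKO stays open: 2 markers (Fcnb and Prtn3) were higher in DKO and Retnlg lower, but adjusted over the list alone 1 rose and 0 fell, and Retnlg missed the threshold without WT 1 (adjusted p = 0.195). Carry-over of less mature neutrophil precursors in DKO and expression within the erythroid cells were not tested.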
